A study of Rattus norvegicus with 16 samples.

How the data were processed

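Per the labels' protocols, left ventricles were frozen and ground in liquid nitrogen, RNA was isolated with Trizol, and small RNA libraries were made with a TruSeq small RNA kit from pools of 2 to 3 rats, 2 pools per condition, and sequenced on an Illumina HiSeq instrument. Surgery took place at 10 weeks of age. The submitters' processing notes name cutadapt, Bowtie and DESeq without versions. The genome build, the miRNA annotation, the trimming and mapping settings and the tool that counted reads are not given in the sources used here, nor is how reads that match several miRNAs or loci were shared.

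The deposited tables, 1 per week, hold raw read counts per library and were not normalized by the authors, per the file headers and the whole numbers in them. Each entry is a rat miRNA, a miRNA named for another species or a genomic locus, and the same reads can stand in several entries: the sums of the tables are therefore not read totals. The tables of weeks 2, 4 and 5 each had 358 rat miRNAs, 150 miRNAs named for other species and 386 loci, and that of week 7 had 325, 104 and 202. Rat miRNAs held 39.1% to 54.4% of the summed counts and the 5 most abundant held 48.3% to 59.5% of the counts on rat miRNAs. The authors also deposited, per the file headers, p-values of their DESeq test of 5/6Nx against sham within each week, raw and Benjamini-Hochberg adjusted, and log2 fold changes, which correlated with the changes computed here at r = 0.995 to 0.999 across miRNAs. A further deposited table gives reads and percent of mapped reads per library: 2214038 to 13480436 reads, of which 70.1% to 92.7% mapped, and the deposited percent equalled the share computed from its read numbers (mean 84.9% for both). The mapped percent was lower in both 5/6Nx pools than in both sham pools at weeks 2 and 7, and reads per distinct sequence were higher at weeks 4, 5 and 7. Counts on rat miRNAs were lower in both 5/6Nx pools at week 2 and higher at weeks 5 and 7. The count tables name the pools A and B and the sample titles number the replicates. That the letters follow the numbers is not stated, so pools are named here by letter and no table of mapping rates was joined to them.

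Before the data were examined, the groups, the tests, 14 lists of miRNAs, the rule for named miRNAs and most alternatives were fixed. The set of entries to test was chosen after the files and the authors' p-values had been seen, and before any test was run here: the 317 rat miRNAs listed in all 4 tables. Entries named for other species and loci were left out of the tests and library sizes because they can repeat the reads of rat miRNAs. Both were brought back as alternatives, whatever these gave.

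edgeR 4.0.16 (R 4.3.3) was run on the counts of all 16 libraries in one fit with a mean for each of the 8 groups, so that the spread is pooled over groups. It used TMM scaling and its filter by group with a minimum count of 10, which kept 306 miRNAs. The quasi-likelihood F test was followed by Benjamini-Hochberg adjustment over the 306 miRNAs within each comparison. The comparisons were 5/6Nx against sham in each week and for the mean of the 4 weekly differences, an interaction test with 3 degrees of freedom, and a test with 3 degrees of freedom of differences between weeks among sham groups. The threshold was an adjusted p under 0.05. The SE of a log2 change was taken as its size over the root of the F value. The common dispersion was 0.0271. Tests are two-sided. CPM used the TMM library sizes. For groups with 1 to 3 counts in both pools together, the ratio scaled by TMM library size has an exact conditional 95% interval. It covers counting error only, since the reads carry no molecular identifiers.

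Lists with 3 or more measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between miRNAs, adjusted over the 14 lists within a comparison, and with fry. They were: cardiomyocyte myomiRs, miRNAs raised and lowered in pressure-overload hypertrophy, fibroblast and profibrotic, antifibrotic miR-29 and miR-30, leukocyte, erythrocyte and blood, endothelial, smooth muscle, the Dlk1-Dio3 cluster, the miR-17-92 family, let-7, hypoxia and p53, and miRNAs of other organs. Members come from general knowledge of these miRNAs, and heart tissue also expresses many of those listed for other cell types. Named are, first, in each comparison of surgery, up to 10 per direction with the largest change among those that passed and whose pools did not overlap (for the mean, with the same sign in all weeks), filled up to 5 per direction with those of smallest p. Named are also 22 miRNAs whatever their test says, members of a list that passed, and the 10 most abundant. Pairs of miRNAs were taken as near-identical where their counts kept a fixed ratio within 10% in every library: miR-378a-3p and miR-3557-5p, miR-378a-5p and miR-3557-3p, miR-125b-5p and miR-3588, miR-151-5p and miR-3586-3p, let-7d-5p and miR-3596b, miR-338-3p and miR-3065-5p, miR-29b-3p and miR-3587, and miR-434-3p and miR-3543. This tolerance was narrowed to 10% after a wider one had been run. Values of these miRNAs are uncertain, since the counting could give the same reads to both.

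The scripts were tested on simulated counts with the means and library sizes of these libraries and 200 changed miRNAs. At week 7, 62.5% of 2-fold changes among 305 miRNAs and 87% of 3-fold changes among 303 were recovered. At week 5 this was 84% of 2-fold changes among 304, and for the mean over weeks 82% of 1.5-fold changes among 305. The simulation gave every group the same spread per miRNA, as pooled over groups. Fitted alone, week 5 had a dispersion of 0.0625, against 0.0108 to 0.0139 in the other weeks. With 200 changed miRNAs the adjustment is also more lenient than with few. The shares recovered may therefore be too high for the real data, above all at week 5. With no change simulated, none of the 301 miRNAs was called in any comparison. That was a single draw with the same spread in every group, so it does not test the uneven spread of the real pools. In the simulations with changes, 0 to 9 unchanged miRNAs were called. The most were 9 of 106 for the mean over weeks at 1.5-fold and 8 of 105 at week 7 at 2-fold.

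The alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, RLE size factors and library totals in place of TMM, no filter, a filter on a mean of 50 counts, each library left out in turn, the pool letter as a block within weeks, each week fitted alone, the authors' deposited p-values, a threshold of 0.1, an estimated correlation in camera, and library sizes without the 5 most abundant miRNAs. Added after the data had been seen were the other sets of entries, a block with letters exchanged in week 7, and fits without week 5 or week 7. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A fit that leaves out a library leaves its group with 1, which is then assumed to vary like the other groups.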

Results

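Small RNA was sequenced from the left ventricle of male Sprague Dawley rats at 2, 4, 5 and 7 weeks after the excision form of 5/6 nephrectomy (5/6Nx), in which most of the kidney mass is removed, or after sham surgery. The series title places the work in cardiorenal syndrome type 4, heart disease that follows chronic kidney disease. Each of the 8 groups of surgery and week held 2 libraries (pools A and B), and each library came from a pool of 2 to 3 rats, which gave 16 libraries. Beyond that label nothing states whether the pools of a group came from different rats, so the p-values measure the spread between these pools. The deposited tables summed to between 1692936 counts (week 7 sham pool B) and 7946533 counts (week 5 5/6Nx pool B) per library. Counts on rat miRNAs were between 1239829 and 2795801 per library at week 2, 1600062 and 3509916 at week 4, 2658563 and 3462488 at week 5, and 672077 and 1625699 at week 7. Levels of the 306 rat miRNAs tested are given in CPM (counts scaled to equal library size, mean ± SD, n = 2 pools per group unless stated). Changes are log2 of 5/6Nx over sham ± SE from edgeR.

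The 10 miRNAs with the highest mean level over the 16 libraries were miR-143-3p at 220369 CPM, miR-22-3p at 153213 CPM, miR-30a-5p at 75855 CPM, miR-133a-3p at 52571 CPM and miR-26a-5p at 49458. They were followed by miR-27b-3p at 48909 CPM, miR-126a-5p at 33071 CPM, miR-181a-5p at 27237 CPM, miR-191a-5p at 26029 CPM and miR-10a-5p at 25443 CPM. They include the muscle miRNA miR-133a, the smooth muscle miRNA miR-143 and the endothelial miRNA miR-126. None of the 10 passed the edgeR test in any comparison of surgery. The log2 changes for the mean over weeks were between -0.25 ± 0.08 for miR-133a-3p and 0.10 ± 0.07 for miR-27b-3p. The sign for miR-143-3p, miR-126a-5p, miR-26a-5p and miR-191a-5p, with changes of 0.08 ± 0.17, -0.15 ± 0.20, -0.03 ± 0.08 and -0.03 ± 0.20, turned under at least 1 other setting. On the first principal component, which held 36.4% of the variance of log CPM, the 4 week 7 libraries had scores of 8.05 to 8.58 and the other 12 libraries scores of -6.38 to 0.08. Within week 5, sham pool A correlated with sham pool B at r = 0.979 across miRNAs, below its correlations of 0.987 to 0.993 with the week 4 libraries.

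At 2 weeks, miR-145-5p, a smooth muscle miRNA transcribed together with miR-143, was 1.71-fold higher after 5/6Nx, with 1201 ± 70.2 CPM against 701 ± 89.1 CPM in sham (log2 0.78 ± 0.15, edgeR adjusted p = 0.0259). miR-201-5p was 2.00-fold lower, with 54.2 ± 3.86 against 108 ± 22.8 CPM (log2 -1.0 ± 0.20, adjusted p = 0.0259). These were the 2 of 306 miRNAs that passed at week 2. At an unadjusted p under 0.05 there were 64. Both 5/6Nx pools lay above or below both sham pools for 185 miRNAs, where chance gives 33.3% of the 306. Mapped reads were 70.1% and 79.0% after 5/6Nx against 82.7% and 88.5% in sham, and both 5/6Nx pools had fewer counts on rat miRNAs. Surgery is not separated from these differences within week 2. The miRNAs with the next smallest p did not pass. On the higher side, miR-3574 had a log2 change of 0.64 ± 0.16, miR-23b-3p of 0.77 ± 0.20, miR-210-3p, a miRNA induced by hypoxia, of 0.57 ± 0.15 (edgeR adjusted p = 0.0649 for all 3). That of miR-21-3p was 1.20 ± 0.32 (adjusted p = 0.0652). On the lower side, miR-328a-3p had -1.04 ± 0.26, miR-22-3p -0.64 ± 0.16, miR-133a-5p -0.64 ± 0.16 (adjusted p = 0.0649 for all 3) and miR-351-5p -0.53 ± 0.16 (adjusted p = 0.0934).

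Of the lists of miRNAs fixed beforehand, the one of miRNAs raised in pressure-overload hypertrophy passed camera at week 2, with 14 of 17 measured members above sham (median log2 0.38, adjusted p = 0.0480). Camera gave an adjusted p = 0.584 with an estimated correlation and fry, which does not compare a list with other miRNAs, an adjusted p = 0.141. By fry the miR-17-92 family passed instead (adjusted p = 0.0424, camera adjusted p = 0.171). Of the members of the list raised in pressure-overload hypertrophy none passed over all miRNAs in edgeR, and 2 passed upward adjusted over the list alone. All 9 measured members of the let-7 family lay below sham (median log2 -0.24), which did not pass (camera adjusted p = 0.0504). In the smooth muscle list miR-145-5p was the 1 of 4 measured members to pass, and camera gave an adjusted p = 0.441 for the list. The count of 2 miRNAs became 53 without week 5 sham pool A and 56 without week 5 sham pool B. It was 4 without week 2 sham pool A and 1 without week 2 5/6Nx pool B or week 4 sham pool A. It was 0 in edgeR (25 to 63 at an unadjusted p under 0.05) without week 2 sham pool B, week 2 5/6Nx pool A, week 4 sham pool B or any of the 4 5/6Nx pools of weeks 4 and 5. The list of raised miRNAs was lost without week 2 sham pool B (adjusted p = 0.355), week 2 5/6Nx pool A (0.513), week 4 sham pool A (0.0600) or B (0.0556), week 5 5/6Nx pool B (0.0532) or week 7 5/6Nx pool A (0.0553), and with library sizes without the 5 most abundant miRNAs (0.0511).

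At 4 weeks, let-7d-5p fell from 1501 ± 96.3 CPM in sham to 850.2 ± 106 CPM after 5/6Nx, a level 1.76-fold lower (log2 -0.82 ± 0.13, edgeR adjusted p = 0.00323). miR-3596b, which passed with a log2 change of -0.84 ± 0.13 (adjusted p = 0.00323), had counts within 10% of a fixed ratio to those of let-7d-5p in every library. Both can hold the same reads and are taken here as 1 signal. No other miRNA passed, and 22 of 306 had an unadjusted p under 0.05. The pools of the groups did not overlap for 136 miRNAs, where chance gives 33.3% of the 306. Among those that did not pass, the NF-kB-induced miRNA miR-146b-5p had a log2 change of 0.61 ± 0.19 and miR-542-3p of 0.61 ± 0.21. Those of miR-125b-1-3p, miR-335 and miR-21-5p were 0.58 ± 0.24, 0.87 ± 0.37 and 0.33 ± 0.14. The lower ones were miR-499-3p (-0.53 ± 0.16), the p53-induced miRNA miR-34a-5p (-0.52 ± 0.17) and miR-3571 (-0.53 ± 0.17). The edgeR adjusted p of these 8 was 0.425 to 0.528. The authors' deposited table for week 4 had adjusted p-values under 0.05 for let-7d-5p, miR-3596b and miR-146b-5p.

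All 9 measured members of the let-7 family lay below sham at 4 weeks (median log2 -0.17), and camera called the list lower with an adjusted p = 0.0421 and an adjusted p = 0.463 with an estimated correlation (fry adjusted p = 0.0905). 1 member, let-7d-5p, passed, both over all miRNAs and adjusted over the list alone. Of the cardiomyocyte miRNAs, 7 of 9 lay below sham (median log2 -0.30), which did not pass camera (adjusted p = 0.0699) but passed fry (adjusted p = 0.0481). The 2 calls at week 4 were lost without week 4 sham pool A or without week 4 5/6Nx pool B (0 in edgeR, with 15 and 9 at an unadjusted p under 0.05). The count was 4 without week 5 sham pool B. The let-7 call was lost in 15 of the 16 fits that left out 1 library, with adjusted p-values from 0.0581 to 0.181, all but the one without week 7 sham pool B. It was also lost with the pool letter as a block (adjusted p = 0.103) and with library sizes without the 5 most abundant miRNAs (0.0996).

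At 5 weeks no miRNA passed in edgeR, where the smallest adjusted p was 0.0635 and 27 of 306 miRNAs had an unadjusted p under 0.05. DESeq2 passed 3 rat miRNAs, limma-voom passed 0, and 0 passed in the authors' deposited table. The pools did not overlap for 107 of 306, where chance gives 33.3%. The smallest p belonged to miR-146b-5p, which had 418 ± 32.5 CPM after 5/6Nx and 799 ± 145 CPM in sham (log2 -0.93 ± 0.19, adjusted p = 0.0635). Next came miR-21-3p, the lesser arm of miR-21, with a log2 change of 1.54 ± 0.35 and miR-146a-5p, an inhibitor of Toll-like receptor signalling, with -1.0 ± 0.23 (edgeR adjusted p = 0.0694 for both). The others had an adjusted p of 0.171. The higher ones were miR-92a-3p (0.67 ± 0.20), miR-3543 (0.67 ± 0.21), miR-351-5p (0.55 ± 0.16) and miR-24-2-5p (0.48 ± 0.15), and the lower ones miR-3068-5p (-1.13 ± 0.31), miR-24-3p (-0.71 ± 0.21) and miR-10a-5p (-0.59 ± 0.18). Sham pools A and B held 136 and 62 counts of miR-3068-5p, 6288 and 3517 of miR-24-3p, and 6756 and 3349 of miR-146a-5p. The 5/6Nx pools held 45 and 58, 2823 and 4063, and 2405 and 3372. The falls of these miRNAs thus rest in large part on sham pool A. Counts of miR-146b-5p were not higher in that pool (2047 and 2449 in sham pools A and B).

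In the fibroblast and profibrotic list 10 of 12 measured members lay above sham at 5 weeks (median log2 0.23). Camera called it higher (adjusted p = 0.0232, adjusted p = 0.427 with an estimated correlation, fry adjusted p = 0.0240). In it 0 members passed over all miRNAs in edgeR and 2 passed upward adjusted over the list alone. Among leukocyte miRNAs 1 member passed upward and 2 downward adjusted over the list alone, with a camera adjusted p = 0.991. The week 5 count became 13 without sham pool A of that week and 63 without sham pool B. It was 2 without either week 2 5/6Nx pool and 1 without either week 7 5/6Nx pool. The fibroblast call was lost without week 5 sham pool A (adjusted p = 0.581) or B (0.224), week 5 5/6Nx pool B (0.269), week 4 5/6Nx pool B (0.0642) or week 7 5/6Nx pool A (0.0549) or B (0.0571).

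At 7 weeks, miR-21-5p, an abundant miRNA of fibroblasts and inflammatory cells, rose 2.77-fold after 5/6Nx, from 4291 ± 40.3 to 11891 ± 141 CPM (log2 1.47 ± 0.14, edgeR adjusted p = 1.4e-05). miR-146b-5p rose 3.49-fold, from 1435 ± 82.2 to 5011 ± 1068 CPM (log2 1.80 ± 0.19, adjusted p = 2.72e-05). miR-208b-3p, which lies in an intron of the beta-myosin heavy chain gene Myh7, rose 2.79-fold, from 1486 ± 219.8 to 4139.6 ± 364 CPM (log2 1.48 ± 0.22, adjusted p = 0.000536). miR-221-3p, which targets the cell cycle inhibitor p27, rose 2.71-fold, from 119 ± 1.51 to 321 ± 45.5 CPM (log2 1.44 ± 0.19, adjusted p = 0.000259). miR-132-3p, which with miR-212 promotes hypertrophy of cardiomyocytes, rose 3.36-fold, from 22.2 ± 5.54 to 76.3 ± 4.02 CPM (log2 1.75 ± 0.31, adjusted p = 0.00368).

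In all, 13 of 306 miRNAs passed at week 7, 10 upward and 3 downward. The counts on rat miRNAs were 1073616 and 672077 in the sham pools and 1625699 and 1365890 in the 5/6Nx pools of that week. In the table of mapping, reads per distinct sequence were 14.559 and 10.842 in sham and 21.005 and 20.347 after 5/6Nx, and 92.7% and 91.3% of reads mapped in sham against 87.6% and 89.3%. Surgery is not separated from these differences within week 7. miR-193-3p rose as well (log2 1.65 ± 0.32, edgeR adjusted p = 0.00651), as did miR-21-3p (1.5 ± 0.32, adjusted p = 0.0103). Further rises were those of the myeloid miRNA miR-223-3p (1.19 ± 0.24, adjusted p = 0.00733) and of miR-199a-5p (0.91 ± 0.19, adjusted p = 0.00756). miR-511-3p, which lies in an intron of the macrophage mannose receptor gene, rose by a fitted 2.54 ± 0.61 (adjusted p = 0.0229). Its counts were 3 in both sham pools together and 33 in the 5/6Nx pools. Scaled by TMM library size this is a ratio of 5.94, with a 95% interval of 1.86 to 30.2 for counting error alone. miR-9a-5p fell from 211 ± 0.176 to 92.1 ± 2.58 CPM (log2 -1.20 ± 0.23, adjusted p = 0.00651). miR-181d-5p (-0.59 ± 0.14, adjusted p = 0.0180) and miR-300-3p (-1.75 ± 0.42, adjusted p = 0.0229) fell too. miR-300-3p had only 24 counts in the sham pools and 13 in the 5/6Nx pools. Below the threshold stayed miR-181b-5p (-0.57 ± 0.16, adjusted p = 0.0557) and miR-3065-3p (-1.87 ± 0.45, adjusted p = 0.0584). At an unadjusted p under 0.05 there were 61 miRNAs. The pools did not overlap for 168, where chance gives 33.3%, the 13 that passed included. The week 7 count was 5 without sham pool A of that week (miR-21-5p, miR-146b-5p, miR-208b-3p, miR-221-3p and miR-132-3p). It was 7 and 8 without 5/6Nx pool A or B, and 44 and 49 without week 5 sham pool A or B, of which 23 and 22 were upward. miR-511-3p, miR-300-3p, miR-21-3p and miR-181d-5p lost their calls without any 1 of the 4 week 7 pools, and miR-199a-5p without either sham pool. miR-9a-5p lost it without sham pool A or either 5/6Nx pool, and miR-193-3p and miR-223-3p lost it without sham pool A or 5/6Nx pool A. miR-300-3p lost it also without week 4 sham pool A.

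**Figure D1:**
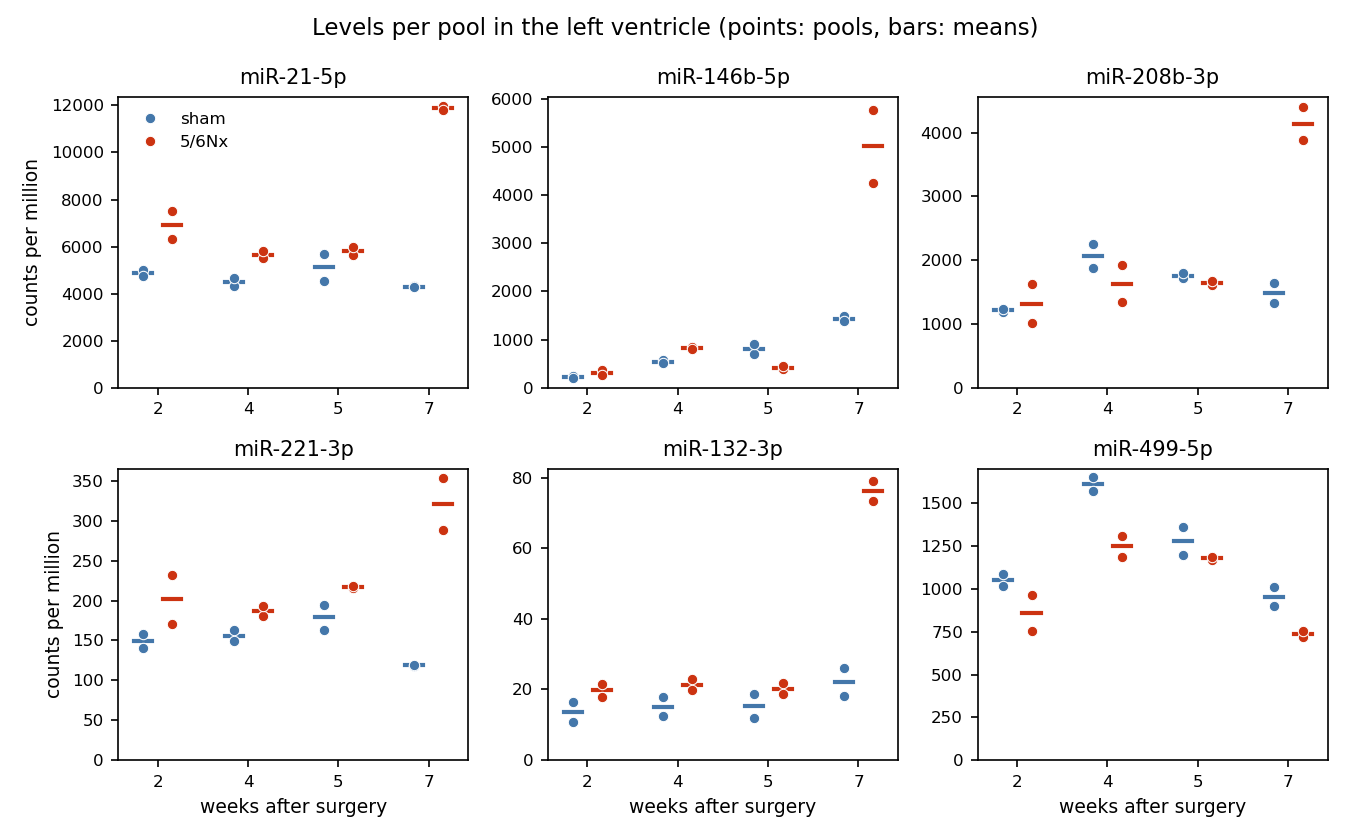
CPM (counts scaled to equal library size, vertical axes, linear from 0) of 6 miRNAs in each pool at 2, 4, 5 and 7 weeks (horizontal axes), sham in blue and 5/6Nx in red, with points for the 2 pools of a group and bars for their mean. At week 7 miR-21-5p lay at 11891 ± 141 CPM after 5/6Nx and 4291 ± 40.3 CPM in sham (mean ± SD).

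**Figure D2:**
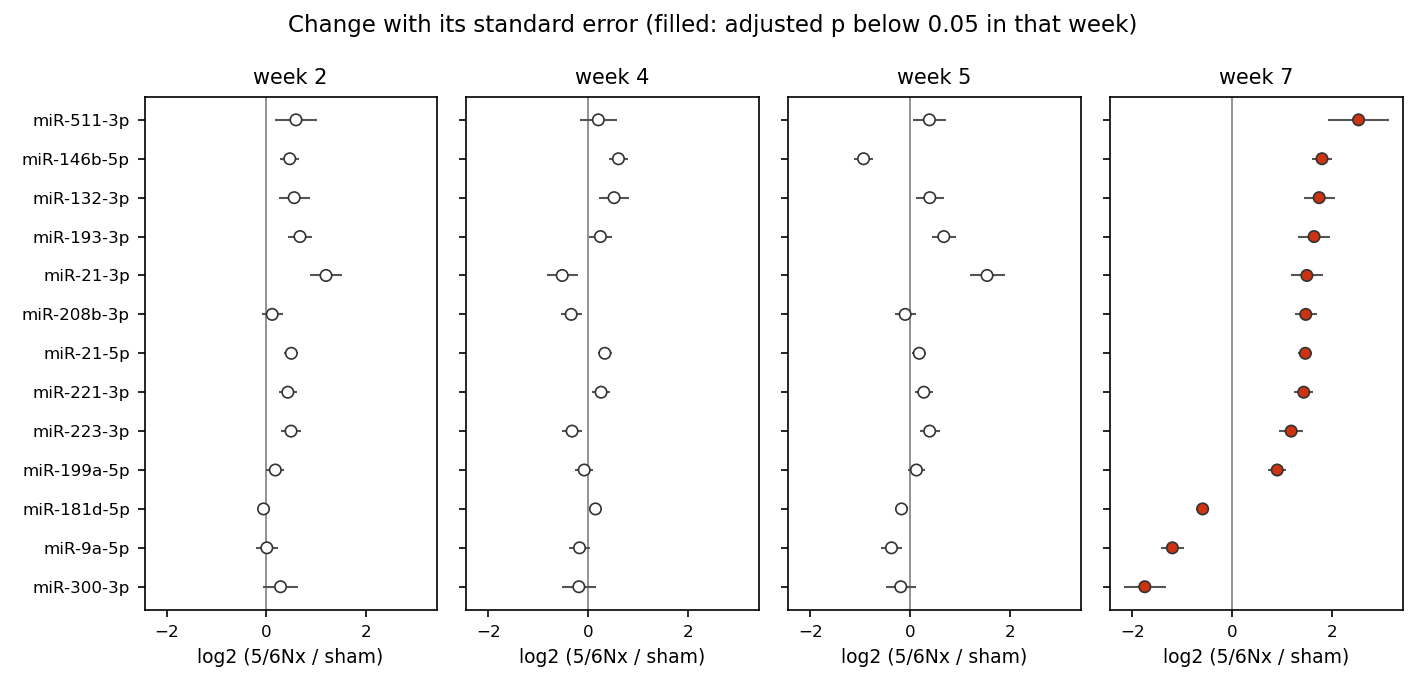
Log2 change of 5/6Nx over sham (horizontal axes) with its standard error (bars) in the 4 weeks for the 13 miRNAs that passed at week 7; filled points mark an edgeR adjusted p under 0.05 in that week. The points are filled for all 13 at week 7 and for none of them at the other weeks.

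Several lists rose together at 7 weeks. In the leukocyte list 11 of 12 measured members lay above sham (median log2 1.23). In it, 5 members passed upward (miR-511-3p, miR-146b-5p, miR-21-3p, miR-21-5p and miR-223-3p), with 6 upward and 1 downward adjusted over the list alone. Camera gave an adjusted p = 4.9e-07, and 0.00308 with an estimated correlation. Other leukocyte miRNAs did not pass, among them miR-155-5p (1.26 ± 0.35, edgeR adjusted p = 0.0557) and miR-142-3p (0.38 ± 0.27, adjusted p = 0.485). The other arm, miR-142-5p, had a log2 change of 0.13. The member below sham was miR-150-5p (log2 -0.48). In the fibroblast and profibrotic list 11 of 12 lay above sham (median log2 0.89). In it, 5 members passed upward (miR-132-3p, miR-21-3p, miR-21-5p, miR-221-3p and miR-199a-5p), with 10 adjusted over the list alone. The list passed (camera adjusted p = 1.49e-11, and 0.00308 with an estimated correlation). All 17 members of the list raised in pressure-overload hypertrophy lay above sham (median log2 0.64). 5 passed upward (miR-132-3p, miR-208b-3p, miR-21-5p, miR-221-3p and miR-199a-5p) and 12 did so adjusted over the list alone. The list passed (camera adjusted p = 4.48e-13, and 0.0177 with an estimated correlation). The 3 lists share members, miR-21-5p being in each, so their counts are not independent of each other. Most measured members of the fibroblast list are also in the raised list. These are miR-21-5p, miR-132-3p, miR-199a-3p, miR-199a-5p, miR-214-3p, miR-221-3p, miR-222-3p, miR-34a-5p and miR-125b-5p. Of the members that passed, miR-132-3p, miR-21-5p, miR-221-3p and miR-199a-5p stand in both, so these 2 lists are largely the same signal. The leukocyte list shares both arms of miR-21 with the fibroblast list.

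The other 11 lists did not pass camera at week 7. For the list lowered in pressure-overload hypertrophy, 14 of 18 members lay below sham (median log2 -0.17, camera adjusted p = 0.0551, fry adjusted p = 0.0466). Of the cardiomyocyte miRNAs miR-208b-3p rose and the other 8 of 9 had values below sham without passing (median log2 -0.27, camera adjusted p = 0.546), among them miR-208a-3p (-0.12 ± 0.19) and miR-1-3p (-0.33 ± 0.23). All 7 erythrocyte miRNAs lay below sham (median log2 -0.24, adjusted p = 0.344) and all 4 hypoxia and p53 miRNAs above it (median log2 0.41, camera adjusted p = 0.130, fry adjusted p = 0.00810). In the list of miRNAs of other organs the nerve-rich miRNA miR-9a-5p was the 1 member that passed, with an adjusted p = 0.344 for the list. The camera adjusted p was 0.546 for the antifibrotic miR-29 and miR-30 list, 0.546 for endothelial and 0.821 for smooth muscle miRNAs. It was 0.546 for the Dlk1-Dio3 cluster (11 of 52 listed miRNAs measured), 0.943 for the miR-17-92 family and 0.592 for let-7 miRNAs. Of all 70 camera tests of a list in a comparison, 9 passed. Median, mean and test differed in sign in 9, none of which passed.

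**Figure D3:**
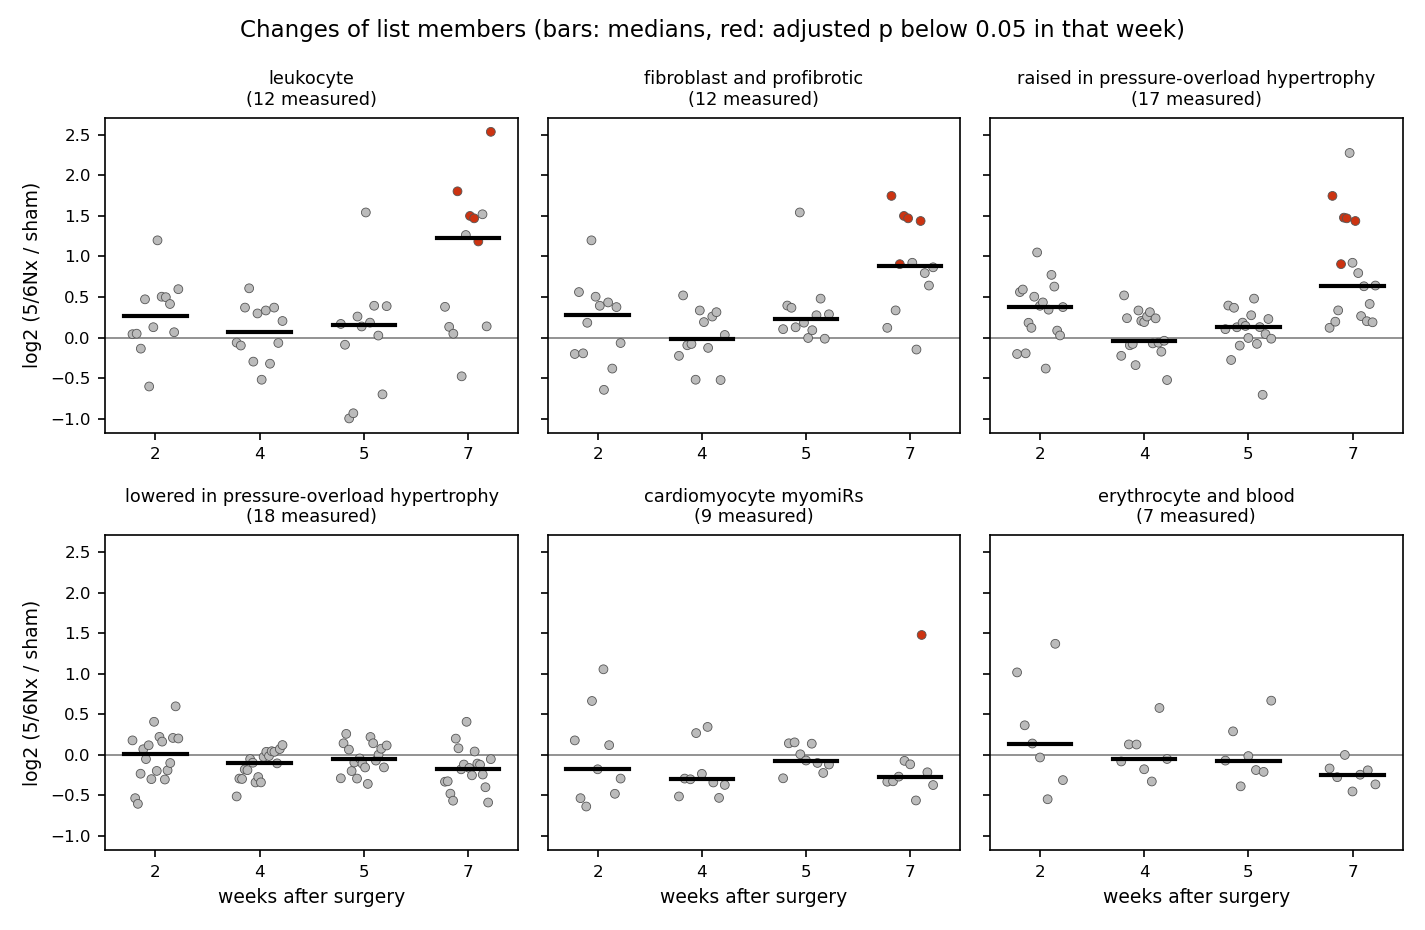
Log2 change of 5/6Nx over sham (vertical axes) at 2, 4, 5 and 7 weeks (horizontal axes) for the measured members of 6 lists, each point a miRNA, black bars the median of the list, and red points an edgeR adjusted p under 0.05 in that week. At week 7 the medians were 1.23 for leukocyte, 0.89 for fibroblast and profibrotic and 0.64 for the list raised in pressure-overload hypertrophy.

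For the mean over the 4 weeks, miR-21-5p was 1.54-fold higher after 5/6Nx (log2 0.62 ± 0.07, edgeR adjusted p = 8.91e-05), with group means above sham in all 4 weeks. The same held for miR-221-3p (0.60 ± 0.09, adjusted p = 0.00154) and miR-193-3p (0.81 ± 0.13, adjusted p = 0.00207), and for miR-132-3p (0.81 ± 0.15, adjusted p = 0.00481) and miR-23b-3p (0.44 ± 0.10, adjusted p = 0.0169). It held too for miR-511-3p (0.93 ± 0.23, adjusted p = 0.0262) and miR-466c-5p (1.03 ± 0.27, adjusted p = 0.0379). Both arms of miR-499, which lies in an intron of the myosin gene Myh7b, were lower after surgery in all 4 weeks. The log2 change was -0.29 ± 0.07 for miR-499-5p (adjusted p = 0.0282) and -0.36 ± 0.08 for miR-499-3p (adjusted p = 0.0169). miR-3065-3p, with -0.80 ± 0.19 (adjusted p = 0.0327), passed as well, at 7 to 25 counts per group. At week 7 the sham pools held 2 counts of miR-466c-5p in sum and the 5/6Nx pools 16. Scaled by TMM library size this is a ratio of 4.32, with a 95% counting interval of 1.01 to 38.7.

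In all, 17 of 306 miRNAs passed for the mean over weeks, 11 upward and 6 downward, and 68 had an unadjusted p under 0.05. The sign was the same in all 4 weeks for 41 of all 306, near the 12.5% that chance gives, and for 10 of the 17. Since the 17 were picked by the mean of the same weekly differences, which favours a shared sign, their share is no separate evidence. Higher among the other 7 were miR-21-3p (0.93 ± 0.16, edgeR adjusted p = 0.00301), miR-146b-5p (0.49 ± 0.09, adjusted p = 0.00614), miR-223-3p (0.44 ± 0.11, adjusted p = 0.0236) and miR-145-5p (0.33 ± 0.07, adjusted p = 0.0169). Lower were miR-201-5p (-0.57 ± 0.10, adjusted p = 0.00301), miR-547-5p (-0.84 ± 0.20, adjusted p = 0.0221) and miR-9a-5p (-0.43 ± 0.11, adjusted p = 0.0294). miR-21-5p, miR-21-3p, miR-146b-5p, miR-221-3p, miR-193-3p and miR-201-5p kept their calls in 27 of 28 alternatives and miR-132-3p in 26 of 27, all but the one without week 7. miR-23b-3p kept its call in 22 of 28, miR-145-5p in 20, miR-499-3p in 19, miR-223-3p in 15, miR-499-5p in 13 and miR-9a-5p in 10 of 28. Of 27 alternatives, miR-547-5p kept it in 19, miR-511-3p in 18, miR-466c-5p in 11 and miR-3065-3p in 9. With the week 7 libraries left out, none of the 17 passed and the count for the mean of the other 3 weeks was 0 in edgeR (42 at an unadjusted p under 0.05). With the week 5 libraries left out it was 58, 27 upward and 31 downward. The count was 8 without week 2 sham pool B, week 4 sham pool B or week 4 5/6Nx pool B, and 9 without week 5 5/6Nx pool B or week 7 sham pool A. It was 11 without week 5 5/6Nx pool A, and 50 and 68 without week 5 sham pool A or B, of which 20 and 25 were upward.

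Other miRNAs with known roles in the heart did not pass for the mean over weeks (adjusted p in parentheses). miR-208b-3p had a log2 change of 0.29 ± 0.11 (edgeR adjusted p = 0.113), which turned to -0.12 without week 7. miR-208a-3p, from an intron of the alpha-myosin heavy chain gene Myh6, had -0.15 ± 0.09 (0.381). The muscle miRNAs miR-1-3p and miR-133a-3p had -0.24 ± 0.11 (0.227) and -0.25 ± 0.08 (0.0747). Of fibroblast and matrix miRNAs, miR-199a-5p had 0.28 ± 0.09 (0.0676), miR-214-3p 0.37 ± 0.12 (0.0741) and the collagen regulator miR-29b-3p 0.11 ± 0.12 (0.631). miR-212-3p, at 5 counts in the week 7 sham pools and 45 in the 5/6Nx pools, had 0.92 ± 0.35 (0.137). Of immune miRNAs, miR-155-5p had 0.46 ± 0.15 (0.0747) and miR-142-3p 0.13 ± 0.12 (0.555). The erythrocyte miRNAs miR-451-5p and miR-144-3p had 0.39 ± 0.19 (0.243) and 0.17 ± 0.18 (0.596). The endothelial miR-126a-3p had -0.14 ± 0.08 (0.366), miR-34a-5p 0.12 ± 0.09 (0.435) and miR-210-3p 0.25 ± 0.07 (0.0578). The signs for miR-29b-3p and miR-34a-5p also turned without week 7, to -0.0066 and -0.07.

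For the mean over the 4 weeks the leukocyte list had 8 of 12 measured members above sham, and 5 that passed upward. It had 6 upward and 1 downward adjusted over the list alone (camera adjusted p = 9.43e-05, and 0.0153 with an estimated correlation). The fibroblast and profibrotic list had 10 of 12 above sham, and 4 that passed upward. It had 6 upward and 1 downward adjusted over the list alone (camera adjusted p = 8.71e-08, and 0.0153 with an estimated correlation). The list raised in pressure-overload hypertrophy had 4 as well, with 16 of 17 members above sham and 8 adjusted over the list alone (camera adjusted p = 2.3e-08, but adjusted p = 0.0671 with an estimated correlation). The cardiomyocyte list had 2 members that fell, both arms of miR-499, and 1 upward and 4 downward adjusted over the list alone (camera adjusted p = 0.111). No other list passed camera, and the 3 that did share members, as at week 7. By fry the cardiomyocyte list passed (adjusted p = 0.0155), as did the lists lowered in pressure-overload hypertrophy (0.0344) and of hypoxia and p53 (0.0309), beside the 3 lists that passed camera. In single weeks before week 7 the leukocyte list did not pass (camera adjusted p = 0.283, 0.360 and 0.991 at weeks 2, 4 and 5). Nor did the fibroblast list at weeks 2 and 4 (0.441 and 0.471) or the raised list at weeks 4 and 5 (0.415 and 0.635). The list tests for the mean were not run without week 7.

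The interaction test asked whether the effect of surgery varied over the 4 weeks. It passed for 5 of 306 miRNAs (61 at an unadjusted p under 0.05). miR-146b-5p had log2 changes of 0.47 ± 0.19, 0.61 ± 0.19, -0.93 ± 0.19 and 1.80 ± 0.19 at weeks 2, 4, 5 and 7 (edgeR adjusted p = 0.000257). Those of miR-21-5p were 0.50 ± 0.14, 0.33 ± 0.14, 0.18 ± 0.14 and 1.47 ± 0.14 (adjusted p = 0.00745), and those of miR-208b-3p 0.12 ± 0.21, -0.34 ± 0.21, -0.10 ± 0.21 and 1.48 ± 0.22 (adjusted p = 0.00764). For let-7d-5p they were -0.40 ± 0.13, -0.82 ± 0.13, 0.38 ± 0.13 and 0.02 ± 0.13 (adjusted p = 0.00764), and miR-3596b, with nearly the same counts, passed with the same adjusted p. The count was 1 without week 7 5/6Nx pool A, 3 without week 4 sham pool A, week 4 5/6Nx pool B, week 5 5/6Nx pool A or week 7 sham pool A, and 57 and 75 without week 5 sham pool A or B. Across the 306 miRNAs, which are not independent replicates, the changes of different weeks correlated at Pearson's r between -0.16 (weeks 4 and 5) and 0.25 (weeks 2 and 7).

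Among the sham groups alone, 96 of 306 miRNAs differed between weeks (134 at an unadjusted p under 0.05). miR-146b-5p had 226 ± 24.3, 543 ± 48.1, 799 ± 145 and 1435 ± 82.2 CPM in sham hearts at weeks 2, 4, 5 and 7 (edgeR adjusted p = 5.28e-06). miR-145-5p had 701 ± 89.1, 768 ± 76.3, 978 ± 2.55 and 353 ± 30.2 CPM (adjusted p = 0.000119), and miR-1-3p 1904 ± 149, 2984 ± 23.8, 2614 ± 33.7 and 4989 ± 967 CPM (adjusted p = 0.00231). Differences also passed for miR-24-3p (adjusted p = 0.000123), miR-10a-5p (0.000347), miR-146a-5p (0.000347), miR-34a-5p (0.000437), miR-21-3p (0.000496) and miR-208a-3p (0.00766), but not for miR-21-5p (0.402) or miR-133a-3p (0.748). The table of week 7 lists 325 rat miRNAs, against 358 in each of the other 3. Its libraries have 2214038 to 4984951 reads against 6817002 to 13480436. Week and batch cannot be told apart in this comparison. The count was 52 without week 2 sham pool B, 62 without week 7 sham pool A, 63 without week 4 sham pool B, and 161 and 147 without week 5 sham pool A or B.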

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

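The tests chosen only after the results were seen were those of depth, of the week 7 effect against the other weeks, of the loci at 0, and of a swap or a low depth of week 5 sham pool A. The count of other splits and the test of the spread were written before. 5 rules were altered after seeing results: the spread of week 7 had to be clearly and not just barely the smallest, and matches of loci were made stricter after a looser rule had matched 23 of 25 loci unspecifically. The swap test was widened to more libraries, and the surgery explanation of the loci was left undecided unless the matches covered most of them. The tolerance for near-identical miRNAs was narrowed.

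The effect of surgery differed between weeks, by the interaction test in edgeR, for miR-146b-5p (adjusted p = 0.000257), miR-21-5p (0.00745), miR-208b-3p (0.00764), let-7d-5p (0.00764) and miR-3596b (0.00764). Outside the comparisons, the entry cel-miR-39-3p, named for a nematode miRNA often used as a spike-in, held 870 counts in week 2 5/6Nx pool B, against 41 to 65 in the sham libraries and 40 to 98 in all other libraries of weeks 2, 4 and 5.

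In edgeR with all libraries most calls within a week fell in week 7 (13 against 2, 2 and 0), but week 2 had more with DESeq2 (39 against 23), with a mean of 50 counts (12 against 11), without week 5 (48 against 39) and without week 5 sham pool A (53 against 44) or B (56 against 49, with 63 at week 5), so the order of weeks depends on the tool, the filter and week 5. Deeper sequencing is argued against, because the mean count on rat miRNAs in week 7, 1184320.5 per library, was the lowest of the 4 weeks. The dispersion of week 7 fitted alone, 0.0108, was below those of weeks 2 (0.0139), 4 (0.0113) and 5 (0.0625), as a smaller spread would need, but week 4 with nearly the same value had 2 calls, fewer miRNAs were fitted in week 7 (251 against 296), and the shared fit pools the spread, so this stays open. A different effect of surgery at week 7 stays open too: 4 of the 13 miRNAs (miR-21-5p, miR-146b-5p, miR-208b-3p and miR-221-3p) differed at week 7 from the mean of the other weeks, and the other 9 did not pass that test. Those 4 may follow a later stage of the disease, a batch, or depth, since week 7 libraries also differ in depth and table, and within week 7 both 5/6Nx pools were deeper than both sham pools.

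Libraries were split within weeks in 100 of 648 possible ways, the real one included. For the mean over weeks, 3 of these splits gave 17 or more calls. That few argues against chance but, with 2 pools per group, does not exclude it. The real split gave 17 and the highest other split 23. The latter exchanged only week 5 sham pool A with week 5 5/6Nx pool A. Another split, with 18, exchanged only week 4 sham pool B with week 4 5/6Nx pool A.

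Week 5 sham pool A stood apart from its group: its correlation with sham pool B was 0.979, with the week 5 5/6Nx pools 0.983, and with the week 4 libraries 0.987 to 0.993, and its score on the second principal component was -7.12 against 2.59 for sham pool B. In the test for a swap, 0 other libraries lay closer to week 5 sham pool B, or to the other week 5 libraries, than to their own partner. That argues against a swap with a library of another week. It cannot settle a swap with a week 5 5/6Nx pool, since nearness to the partner did not separate surgery at week 4. There sham pool B correlated at 0.9958 with 5/6Nx pool A and at 0.9948 with its own partner. Low depth is argued against as well, since the lowest of the other 3 week 5 libraries had only 1.03 times its counts on rat miRNAs. A single wrong label, an exchange with a sample outside this series, or a pool of rats that differed may each account for it and were not tested.

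By the adjusted p in the authors' deposited tables, 40 entries passed, 8 rat miRNAs and 32 loci, and 25 of the loci had 0 counts in both libraries of a group. The tables give positions such as chromosome 10, 62782730 to 62782812, at 0 in both week 2 sham libraries and 134657 and 184016 counts in the 5/6Nx libraries, in a genome build that is not given in the sources used here. That the reads of such a locus were counted under another entry could account for part. Of 25 loci, 12 had an overlapping locus or a rat miRNA (9 and 7 of them) with matching counts. Matching counts lay within 10% of those of the locus where it was above 0 (for miRNAs, where it had 10 or more). The matching entries also held reads where the locus was at 0. Random ratios gave 3 matches for the miRNAs, and the locus on chromosome 7 at week 7 matched 4 miRNAs at once. The other 13 loci had no match. Of these, 2 overlap each other with the same counts and are both at 0 in sham. An effect of surgery on the RNA was tested for 6 loci on their matched rat miRNAs (5, since miR-30c-2-3p matched 2 loci), of which 0 passed in the direction of the locus: 3 moved with it without passing, the closest miR-34c-5p at week 7 (0.87 ± 0.27, edgeR adjusted p = 0.0669), and 3 against it, among them miR-22-3p for the locus above (-0.64 ± 0.16, adjusted p = 0.0649). With 6 of 25 loci covered, neither explanation is decided for the loci as a set. For the locus on chromosome 10 given above, miR-22-3p held 136219 and 186331 counts in the 5/6Nx libraries. In the sham libraries, where the locus was at 0, it held 265525 and 505191, so the matching miRNA was not absent from sham.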

How the results depend on the processing

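The tests added after the data were seen are the other sets of entries, the exchanged letters and the fits without week 5 or week 7. Of the calls of single miRNAs, 364 of the values under settings other than a left-out library stayed past the threshold with the same sign and 70 did not; with a library left out it was 414 and 130. No called miRNA changed sign. miR-21-5p, miR-146b-5p, miR-208b-3p and miR-221-3p passed at week 7 under all 30 alternatives. Of the lists, 20 such values stayed past the threshold and 7 did not, and 117 and 27 with a library left out. The causes were not tested.

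At week 2 the count of 2 miRNAs became 39 with DESeq2, 12 with a mean of 50 counts, 4 without a filter or with entries of other species, 5 with the week alone, 21 at an adjusted p under 0.1 and 48 without week 5. It was 0 with library totals (edgeR, 64 at an unadjusted p under 0.05), with loci included (81) and in the authors' table (7). At week 4 the count of 2 became 16 with the week alone, and 15 with the week alone and every rat miRNA of its table. At week 5 the count of 0 became 3 with DESeq2 or at 0.1, 2 without a filter and 1 with a mean of 50 counts. At week 7 the 13 became 23 with DESeq2, 39 without week 5, 34 with the week alone or at 0.1, and 5 in the authors' table. It was 29 with the week alone and every rat miRNA of its table. The 17 for the mean became 30 with DESeq2, 40 at 0.1, 58 without week 5 and 0 without week 7 (edgeR, 42 at an unadjusted p under 0.05). The 5 of the interaction became 27 with DESeq2, 3 with loci included and 19 without week 5. The 9 list calls became 5 with an estimated correlation, 8 with the block by letter (without let-7 at week 4) and 7 with library sizes without the 5 most abundant miRNAs (also without the raised list at week 2). The calls for the mean, 11 upward and 6 downward, were 14 and 3 with library totals, 16 and 14 with DESeq2, 12 and 12 without a filter, 10 and 11 with a mean of 50 counts, 20 and 20 at 0.1 and 27 and 31 without week 5, so the excess of upward calls depends on these. At week 7, 10 and 3 became 20 and 19 without week 5. Library totals moved the median log2 change of all miRNAs by up to 0.101 (week 4).

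Leaving out 1 library gave 0 to 56 calls at week 2, 0 to 4 at week 4, 0 to 63 at week 5, 5 to 49 at week 7, 8 to 68 for the mean, 1 to 75 for the interaction, 52 to 161 for sham weeks and 6 to 11 for lists. For miRNAs the highest counts came without week 5 sham pool A (53, 2, 13, 44, 50, 57 and 161 in that order) or B (56, 4, 63, 49, 68, 75 and 147), whose difference enters the pooled spread. For lists the highest came without week 7 sham pool B (11), against 8 and 9 without week 5 sham pool A or B.

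The data gave no sign that letters A and B pair the pools. Deviations of same-letter pools correlated at 0.0989, -0.0917, 0.0177 and -0.181 in weeks 2, 4, 5 and 7. With 2 pools per group this cannot exclude pairing, on which the labels say nothing. With the replicate block by letter the counts were 0 at week 2 (edgeR, 61 at an unadjusted p under 0.05), 2, 1, 10 and 8 for the mean; letters exchanged in week 7 gave 0 (64), 2, 0, 15 and 10.

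Signs turned only for miRNAs that had not passed, all for the mean over weeks: without week 7 miR-208b-3p -0.12, miR-29b-3p -0.0066 and miR-34a-5p -0.070; with library totals miR-26a-5p 0.023; without week 5 miR-126a-5p 0.083; and miR-191a-5p 0.0036 with DESeq2, 0.0019 with RLE, 0.020 with library totals, 0.049 with limma-voom, 0.052 with either block, 0.0075 with entries of other species and 0.22 without week 5. With a library left out, miR-126a-5p ranged from -0.34 to 0.16, miR-143-3p from -0.087 to 0.32, miR-191a-5p from -0.22 to 0.29 and miR-26a-5p from -0.081 to 0.029. Alternatives for normalized values (pseudocount, low values) were not run, since the tables hold counts. At week 7, with the lowest depth, 12% of simulated 1.5-fold changes among 302 miRNAs were recovered. At weeks 2, 4 and 5 the shares were 23%, 33.5% and 31%, so changes of that size were mostly not detectable in any week taken singly.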

Other observations

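Only the values of r without the precursors farthest on the 3p arm or on both arms were chosen after the result was seen, and miR-21 and miR-499 had been seen moving with both arms before the test of arms was written.

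The hypothesis was that both arms of a precursor follow its amount. Across 73 precursors with both arms measured, the log2 changes of the 5p and 3p arms at week 7 correlated at Pearson's r = 0.529 and Spearman's rho = 0.579 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give), and 49 of 73 had the same sign. Without the 2 precursors farthest from the median on the 5p arm, miR-223 and miR-547, r was 0.532, without those farthest on the 3p arm, miR-10a and miR-425, it was 0.618, and without these 4 it was 0.615. Without miR-21 and miR-499 it was 0.487. The 73 precursors include both miR-378a and miR-3557, whose arms had near-identical counts and can hold the same reads, so their signal may be repeated. miRNAs are not independent replicates, and arms of one precursor may also share library effects, so r = 0.529 is consistent with the hypothesis without deciding it.

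Of other values, miR-451-5p and miR-144-3p, which share a precursor transcript in erythroid cells, had log2 changes of 1.37 ± 0.38 and 1.02 ± 0.36 at week 2 (edgeR adjusted p = 0.0725 and 0.102) and of -0.19 ± 0.39 and -0.17 ± 0.39 at week 7 (adjusted p = 0.842 and 0.853). None of these passed. miR-208a-3p had log2 changes between -0.23 and -0.07 in the 4 weeks, beside 1.48 ± 0.22 for miR-208b-3p at week 7.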
